A study of Homo sapiens with 12 samples.

How the data were processed

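Cells labelled HEL, a human erythroleukaemia cell line, were grown with DMAG, a plant glucoside of a methylated ellagic acid, at 40 µg/ml for 3 days, or as controls. No dose or day is recorded for the controls, and whether they received a vehicle is not given here. There were 3 control and 3 DMAG samples for RNA-Seq and 3 control and 3 DMAG samples for small RNA sequencing. Per the labels' protocols, the RNA-Seq libraries were made from RNA depleted of ribosomal RNA with a dUTP step in the second strand, and the small RNA libraries by adapter ligation. The submitters' processing notes name HISAT2 2.0.4, Bowtie, StringTie 1.3.3 and the genome build GRCh38, with no roles. The counting rules, the caller of circular RNAs and the removal of reads before quantification are not given in the sources used here.

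The authors deposited FPKM values (fragments scaled to transcript length and library total) per transcript for mRNAs, annotated lncRNAs and lncRNAs assembled without an annotated gene. The mRNA table held 83027 transcripts of 19659 genes, of which 4298 genes were 0 in each library. For miRNAs and circular RNAs the authors deposited read counts and TPM. The TPM columns equalled CPM over the column total within 4.9e-11 and 4.2e-10 (largest difference, circular RNAs and miRNAs in turn), so only the counts were tested. No per-sample column was left unused for want of a sample. The depth of the RNA-Seq libraries behind the FPKM values is unknown. The miRNA counts summed to between 4303596 and 6003077 per library, and those of circular RNAs to between 4716 and 5701. A count of 0 in a library allows up to 3 counts, which is 0.500 to 0.697 CPM for miRNA and 526 to 636 CPM for circular RNA. These limits cover counting error only.

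From these values, mRNA transcripts were summed per gene, and 10394 genes with a mean of at least 0.5 FPKM were tested on log2(FPKM + 1) with limma 3.58.1 (empirical Bayes with a mean trend, R 4.3.3). The lncRNA tables were tested per transcript on log2(FPKM + 0.1) at a mean of at least 0.1 FPKM, each table by itself. A log2 change on these scales understates the change of low genes. Counts of miRNAs and circular RNAs were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10 for miRNA and 5 for circular RNA). DESeq2 1.42.0 served as an alternative. Levels of miRNAs are TMM-scaled CPM unless stated otherwise. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Fixed lists, 34 of mRNA genes and 5 of miRNAs, were tested with camera at a preset correlation of 0.01 where at least 5 genes or 3 miRNAs were tested, and also with an estimated correlation. The gene lists were also tested with fry.

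The genes named were set by a rule. For mRNA these were the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM in the higher group and no overlap of the groups, 12 lineage and cell cycle genes whatever their result, and up to 4 members with the smallest p of each list described. For each lncRNA table these were the 4 largest rises and falls at 0.5 FPKM or more, plus up to 6 called members of a lncRNA list. For miRNA these were the 6 largest rises and falls at 10 CPM or more and up to 4 members per list, and for circular RNA up to 4 rises and 4 falls. Genes named outside the rule are marked as chosen after their values were seen, or were named by a test. The design, lists, naming rule and all but 2 alternatives were fixed before the data were examined.

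The steps were tested on simulated data drawn from the spread of these tables. For mRNA, 80.6% of genes changed by 1 on the log2 scale were recovered among 10394. For annotated lncRNAs this was 47.8% among 2746 transcripts, and for miRNA 88.1% among 583. For unannotated lncRNAs, 31.3% of changes of 2 and 77.6% of changes of 4 on the log2 scale were recovered among 5307 transcripts, sizes enlarged after a first simulation with smaller changes recovered none at 2 or less. For circular RNA, 11.8% of changes of 1 and 75.8% of changes of 2 were recovered among 303. There 100 of the 303 were changed in the simulation, while 3 were called in the data, so these shares may overstate recovery. In each other simulation 200 features were changed. Of the simulated calls, 8.3% were false for circular RNA, 6.9% for unannotated lncRNAs, 5.3% for mRNA, 2.1% for annotated lncRNAs and 1.9% for miRNA. Alternatives were other pseudocounts, filters, scalings and tests, values per transcript, a replicate block and leaving out each library in turn. The labels do not say that samples came from separate cultures, so p-values measure only the spread between these samples. No genome sequence was used here, and coordinates are not given.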

Results

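The series measured mRNA, lncRNA, circular RNA and miRNA in cells labelled HEL, a human erythroleukaemia line. The cells had 3 days with 40 µg/ml DMAG, a glucoside from the burnet Sanguisorba officinalis, or were controls with no dose or day recorded. Levels of lineage genes leave open whether the cells were HEL (see Other observations). There were 3 libraries per group for RNA-Seq and 3 per group for small RNA sequencing. The title names slower proliferation and megakaryocytic differentiation as the setting. The small RNA libraries held 4303596 to 6003077 miRNA counts and the RNA-Seq libraries 4716 to 5701 circular RNA reads; the depth behind the FPKM values is unknown. Values are mean ± SD with n = 3 per group unless a library is named. On log2(FPKM + 1), the first principal component held 66.1% of the variance and separated the 3 control from the 3 DMAG libraries. Correlations of libraries across genes were 0.985 to 0.990 within groups and 0.959 to 0.963 between groups, where genes are not independent replicates.

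The first question was which mRNAs differed with DMAG. Of 10394 genes tested, 2333 were higher and 2717 lower with DMAG (limma, adjusted p under 0.05), and 184 of the former and 111 of the latter changed at least by 1 on the log2 scale. The deepest fall was that of CYP1B1 (ENSG00000138061), a cytochrome P450 induced through the aryl hydrocarbon receptor, from 110 ± 2.78 to 3.35 ± 0.0805 FPKM, 32.8-fold lower (log2 change -4.67, SE 0.0387, adjusted p = 9.7e-08). The receptor's targets TIPARP (1.92-fold) and AHRR (2.04-fold) were also lower, while NQO1 was at 9.82 ± 1.90 and 9.62 ± 1.11 FPKM. PRTN3, the granule protease proteinase 3, fell from 916 ± 61.0 to 227 ± 17.3 FPKM. PHGDH, the first enzyme of serine synthesis, fell from 101 ± 6.14 to 25.7 ± 2.72 FPKM, and the cystine transporter SLC7A11 from 14.2 ± 0.504 to 3.80 ± 0.161 FPKM.

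The other large falls by the naming rule were those of IL9R, the interleukin-9 receptor (8.58 ± 0.552 to 0.662 ± 0.0394 FPKM), CHAC1, which degrades glutathione (6.24-fold), B3GNT7 (5.65-fold), the urea cycle enzyme ASS1 (4.34-fold), FUOM (3.81-fold) and the netrin receptor UNC5C (3.72-fold). Among the largest rises was that of TUBA4A, an alpha-tubulin, which was at 32.5, 8.55 and 8.87 FPKM in the control libraries and at 101 ± 6.61 with DMAG (log2 change 2.80, or 3.40 without control replicate 1). ADAMTS20, a secreted protease, rose from 1.09 ± 0.252 to 11.8 ± 1.09 FPKM. The remaining 8 largest rises were 3 mitochondrially encoded mRNAs and 5 genes of ribosomal RNA processing or modification. For these 8, removal of reads from the control libraries alone cannot be told apart from an effect of DMAG (see Other observations). The other 10 mitochondrial mRNAs had a median log2 change of -0.35. Their means ran from MT-ATP6 to MT-CO1, 232 to 4178 FPKM in controls and 172 to 3501 with DMAG, noted after their values were seen. The 3 that rose thus lay below this range in controls and within it with DMAG. MT-CYB rose from 16.2 ± 0.773 to 549 ± 27.3 FPKM, MT-ND5 from 20.9 ± 3.01 to 679 ± 60.7 FPKM, and MT-ND6 rose 22.7-fold. RRP1B rose from 1.32 ± 0.0642 to 39.8 ± 0.248 FPKM, RRP36 28.5-fold, RRP7A 13.4-fold, MRM2 11.2-fold and RRP12 9.99-fold.

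**Figure D1:**
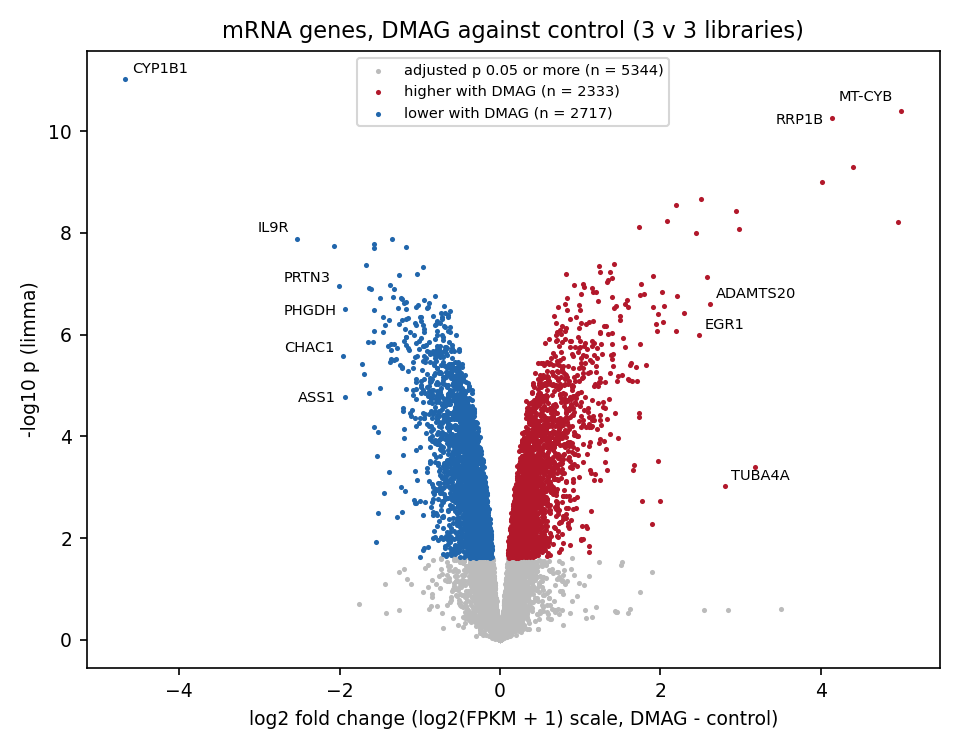
Log2 fold change of each tested mRNA gene on the log2(FPKM + 1) scale (x axis, DMAG minus control) against -log10 of the limma p (y axis); colours mark the 2333 genes higher and 2717 lower with DMAG. CYP1B1 lies at -4.67 and MT-CYB at 5.00. The rise of MT-CYB cannot be told apart from a removal of reads from the control libraries.

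The next question, from the title, was whether megakaryocyte genes rose. Of 45 megakaryocyte and platelet genes, 37 lay below the level tested, and of the other 8, 3 rose, 1 fell and 4 did not pass, the same counts when adjusted over the list alone. The list did not pass as a whole (camera adjusted p = 0.22, and adjusted p = 0.44 with an estimated correlation). The 3 that rose were PLEK, the platelet and leukocyte protein pleckstrin (48.8 ± 1.28 to 93.2 ± 1.47 FPKM), the adhesion receptor CD226 (0.863 ± 0.115 to 4.78 ± 0.706) and the transcription factor NFE2 (3.95 ± 0.527 to 12.1 ± 0.824), while ABCC4 fell 1.54-fold. The platelet receptor genes and PF4 were near 0 in both groups. ITGA2B averaged 0.0826 ± 0.0468 and 0.291 ± 0.0540 FPKM, and GP1BA 0.0305 ± 0.0359 and 0.0755 ± 0.0528. ITGB3 and PF4 were listed at 0 in 5 of the 6 libraries. The exceptions were control replicate 3 for ITGB3 (0.0126 FPKM) and DMAG replicate 3 for PF4 (0.176). The latter is the library with high HBB described below. ITGA2B entered the test only without the filter on low values, where it passed (log2 change 0.25, adjusted p = 0.0078). Of the transcription factor list of the 2 lineages, which also holds NFE2, 9 of 14 tested members rose and 4 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.076, or 0.033 without DMAG replicate 3, and adjusted p = 0.53 with an estimated correlation), with FLI1 at 19.9 ± 1.11 and 28.7 ± 0.729 FPKM (adjusted p = 4.8e-04) and MYB 1.56-fold higher. RUNX1 was 1.13-fold lower (adjusted p = 0.037), a call lost without control replicate 2 or 3 or any 1 of the DMAG replicates (adjusted p between 0.054 and 0.11).

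Of 43 erythroid genes 15 were tested, 6 rose, 3 fell and 6 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.13, or 0.36 without DMAG replicate 3, and adjusted p = 0.44 with an estimated correlation). CA2, a carbonic anhydrase, fell 2.56-fold and SLC25A37, the mitochondrial iron importer, rose 1.54-fold. GATA1 stayed at or below 0.142 FPKM per transcript, a value reached in DMAG replicate 3. Adult globin mRNA was high in DMAG replicate 3 alone, with HBB at 1367 FPKM there, at 0.0731 in DMAG replicate 1 and at 0 in the other 4 libraries; it did not pass the test (adjusted p = 0.34). HBG2 was at 1.69 FPKM in DMAG replicate 3 and at most 0.0475 elsewhere, and HBG1 was at 0.0681 in that library and listed at 0 elsewhere. Of 26 granulocyte genes, 9 lay below the level tested. Levels differed widely among the others: MPO was at 1089 ± 29.1 FPKM in controls and 815 ± 82.9 with DMAG, CLC at 320 ± 14.5 and 523 ± 12.9, ELANE at 17.2 ± 2.47 and 6.92 ± 0.930, and CTSG at 32.1 ± 1.56 FPKM in controls and 2.00-fold lower with DMAG. HBB, MPO, CTSG and ELANE were chosen after their values were seen.

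**Figure D2:**
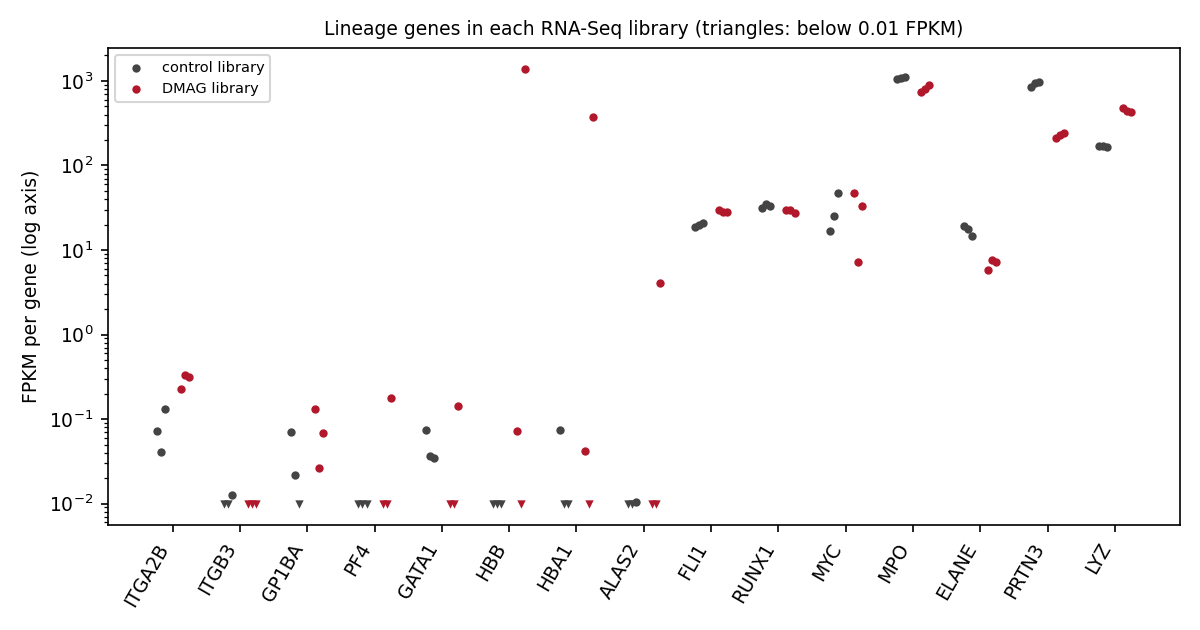
FPKM (log axis) of 15 lineage genes in each of the 3 control (grey) and 3 DMAG (red) RNA-Seq libraries, 1 point per library; triangles mark values below 0.01, and HBB, HBA1, ALAS2, MPO and ELANE were chosen after their values were seen. ITGA2B, ITGB3, GP1BA, PF4 and GATA1 lie below 1 in each library, and HBB reaches 1367 in DMAG replicate 3 alone.

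On proliferation, DNA replication and mitosis genes did not pass as lists. Of 51 DNA replication genes 8 rose, 16 fell and 27 did not pass (camera adjusted p = 0.51, and adjusted p = 0.80 with an estimated correlation), with the helicase subunit MCM4 1.51-fold and the licensing factor CDT1 1.48-fold lower and UHRF1 1.49-fold higher; for MCM4 the most abundant transcript by itself had a log2 change of 0.90 and did not pass. Of 55 mitosis genes 18 rose, 9 fell and 28 did not pass (adjusted p = 0.13, and adjusted p = 0.53 with an estimated correlation), with PTTG1, the securin, 1.40-fold higher and CDC20 1.23-fold lower. For these 2 lists the counts were the same when adjusted over the list alone. Of 13 genes of CDK inhibitors, D-type cyclins and their partners 4 rose, 2 fell and 7 did not pass (6 and 2 adjusted over the list alone), and the list did not pass, with camera pointing up (adjusted p = 0.22, and adjusted p = 0.44 with an estimated correlation). Cyclin D2 (CCND2) fell from 144 ± 0.751 to 72.2 ± 4.10 FPKM and CDK6 fell 1.66-fold, while BTG1 rose 1.72-fold and RBL2, a relative of the retinoblastoma protein, 1.46-fold. MYC had 29.9 ± 16.1 and 29.1 ± 20.3 FPKM (adjusted p = 0.79), and CDKN1A at most 0.328 ± 0.0508 FPKM on average. Of 22 p53 target genes tested 5 rose, 8 fell and 9 did not pass, with 5 and 8 also when adjusted over the list alone. That list did not pass (camera adjusted p = 0.51, and adjusted p = 0.61 with an estimated correlation), with SESN2 2.05-fold lower and TNFRSF10B 1.95-fold higher.

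By camera at the preset correlation, 10 of 32 gene lists passed, 5 lower and 5 higher. A grouping that mixed control and DMAG libraries gave up to 9 (see Other observations). With an estimated correlation none of the 32 passed (smallest camera adjusted p = 0.42, with 3 lists under an unadjusted p of 0.05), while fry called 27. Histone genes had 27 of 32 tested members lower and none higher (28 and none adjusted over the list alone; adjusted p = 2.9e-09, and adjusted p = 0.44 with an estimated correlation); HIST1H1E, a linker histone, went from 449 ± 9.39 to 150 ± 6.73 FPKM, and near-identical histone genes can share reads. Ribosome biogenesis genes had 37 of 45 lower and 3 higher (37 and 4 adjusted over the list alone; adjusted p = 1.9e-07, and adjusted p = 0.42 with an estimated correlation), with DDX21 1.54-fold lower; the 3 that rose were RRP1B, RRP9 and RRP12. Of 45 ribosomal protein genes 16 were lower and 1 higher (adjusted p = 0.0059, and adjusted p = 0.44 with an estimated correlation), RPL3 by 1.85-fold. Of 35 genes of the unfolded protein and integrated stress responses 20 were lower and 2 higher (20 and 3 adjusted over the list alone; adjusted p = 8.2e-04, and adjusted p = 0.44 with an estimated correlation), among them the serine synthesis enzyme PSAT1 (3.09-fold lower). Heat shock genes had 12 of 17 lower and 1 higher (adjusted p = 0.0074, and adjusted p = 0.43 with an estimated correlation), with the mitochondrial chaperonin HSPD1 1.48-fold lower. For the other 2 of these 5 lists the counts were the same when adjusted over the list alone.

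Among the lists that were higher, autophagy and lysosome genes had 17 of 33 higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 1.5e-04, and adjusted p = 0.42 with an estimated correlation), with MAP1LC3B, a marker of autophagosomes, 1.53-fold higher and LAMP2 1.43-fold. Interferon-stimulated genes had 14 of 32 higher and 4 lower (adjusted p = 0.0059, and adjusted p = 0.42 with an estimated correlation); IFI6 was 3.82-fold higher and IFI35 2.56-fold lower. Monocyte and macrophage genes had 9 of 14 higher and 2 lower (adjusted p = 0.0062, and adjusted p = 0.44 with an estimated correlation): LYZ, lysozyme, went from 168 ± 2.61 to 444 ± 26.0 FPKM, TLR4 3.85-fold up and the integrin ITGAM 2.99-fold. Immediate-early and ERK feedback genes had 14 of 32 higher and 3 lower (15 and 3 adjusted over the list alone; adjusted p = 0.0062, and adjusted p = 0.44 with an estimated correlation), with EGR1 8.47-fold and DUSP6 2.31-fold higher. Actin cytoskeleton genes had 15 of 33 higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation), with TPM4 2.75-fold and RAC2 2.36-fold higher. For interferon-stimulated and monocyte genes the counts were the same when adjusted over the list alone.

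**Figure D3:**
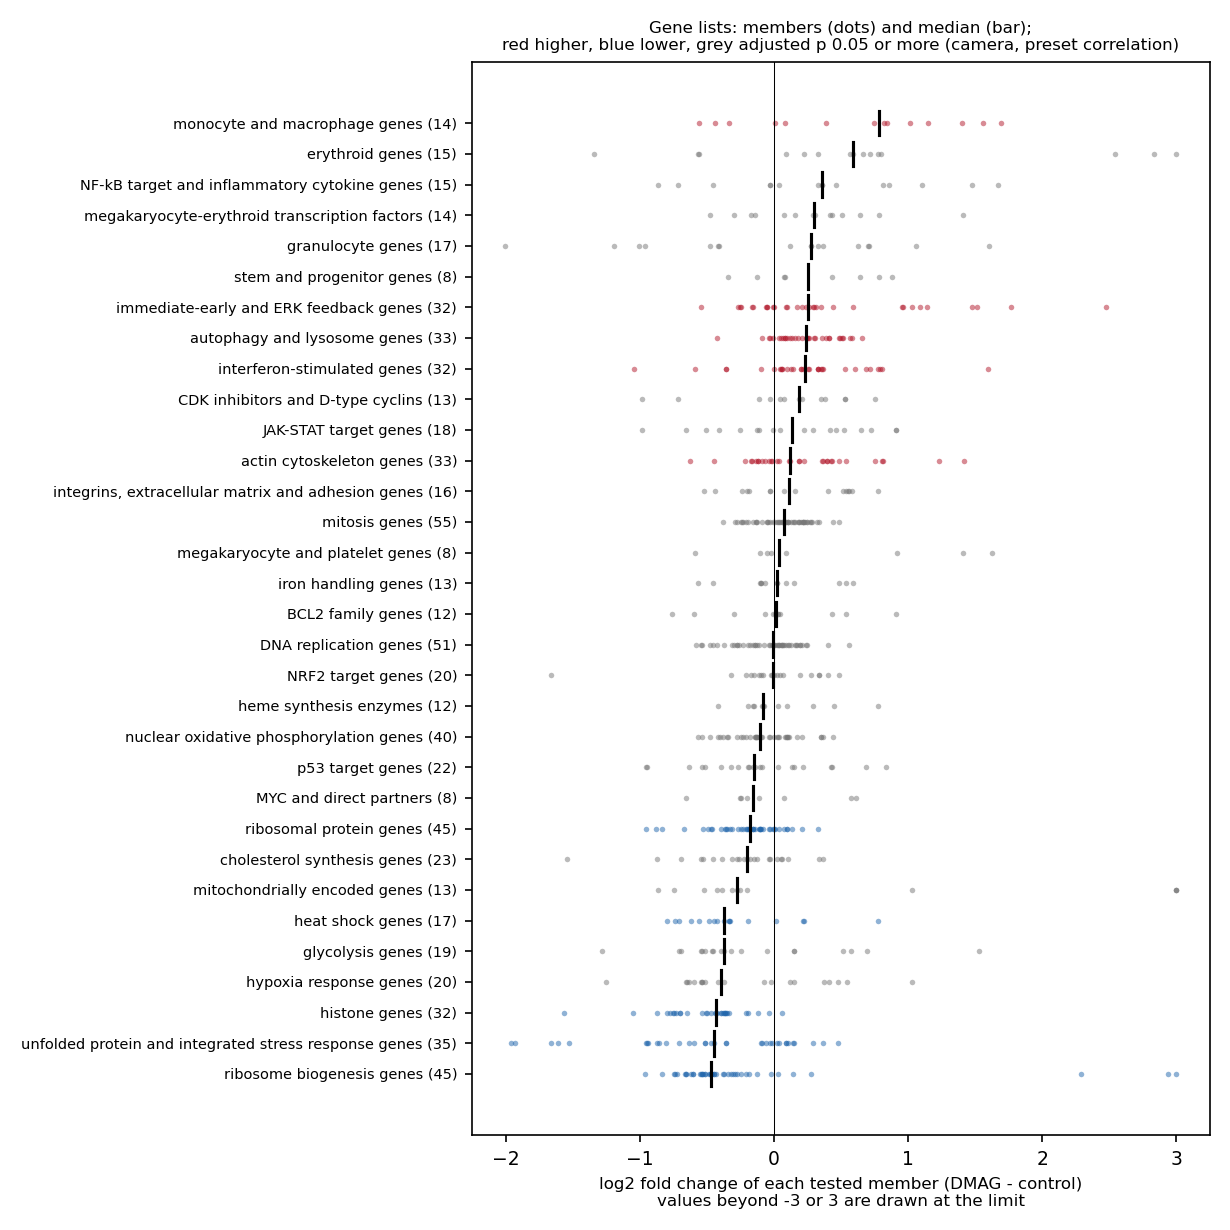
Log2 fold change (x axis, DMAG minus control) of each tested member of the 32 lists with at least 5 tested genes, with the number tested in parentheses and the median as a bar and values beyond 3 drawn at that limit; red and blue mark lists that passed camera at the preset correlation. Histone genes lie nearly all below 0, with a median of -0.44.

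For annotated lncRNAs, 348 of 2746 transcripts were higher and 94 lower with DMAG (limma). The median log2 change of all these transcripts was 0.20, and with libraries scaled to the same median the split was 182 higher and 197 lower. Without DMAG replicate 1, 2 or 3 the count of 442 was 206, 240 or 247. Antisense transcripts gave 149 of the rises and 33 of the falls, and lincRNAs 100 and 27. The 4 largest rises on the log2 scale began with a transcript of RP11-443B7.1, a lincRNA (ENST00000451766.2; 0.167 ± 0.0547 to 9.53 ± 1.17 FPKM). Next came ENST00000439058.5 of AC005083.1, at 0, 0.379 and 0.0140 FPKM in the control libraries and 2.64 ± 0.377 with DMAG. The antisense transcript ENST00000601034.2 was 15.8-fold higher, and a second transcript of RP11-443B7.1 (ENST00000418557.1) went from 0.488 ± 0.117 to 6.96 ± 0.797 FPKM. ENST00000430859.1 of AC005083.1 was instead 5.62-fold lower (adjusted p = 0.033; between 0.067 and 0.097 when 1 of the control replicates or DMAG replicate 1 or 2 was left out). Among the largest falls were a transcript of the snoRNA host gene SNHG12 (1.70 ± 0.309 to 0.258 ± 0.149) and those of AC003029.1 (12.9-fold) and RP5-1171I10.4 (7.97-fold), the last lost without control replicate 2 or 3 or any 1 of the DMAG replicates (adjusted p between 0.056 and 0.069). Of lncRNAs known from blood cells or tumours, 8 of 133 tested transcripts were higher and 20 lower (9 and 24 adjusted over the list alone). Single transcripts fell 3.09-fold (SNHG4), 2.10-fold (MIR17HG, the host of the miR-17-92 cluster), 2.00-fold (SNHG5) and 1.95-fold (SNHG15), and 1 transcript of JPX rose 1.82-fold. The other 4 transcripts of JPX tested went both ways and did not pass, nor did the most abundant transcript of SNHG5, 1.26-fold lower (adjusted p = 0.062).

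Among lncRNAs assembled without an annotated gene, 78 of 5307 transcripts were higher and 35 lower. The median log2 change was -0.44, and after scaling to the same median the split was 114 and 11. The number lower was unstable: without control replicates 1, 2 and 3 in turn there were 66, 72 and 57 higher and 9, 7 and 9 lower. Without DMAG replicates 1, 2 and 3 there were 50, 51 and 53 higher and 14, 16 and 45 lower, and at a mean of at least 0.5 FPKM 83 and 78. Of the rises 76 were among 1016 lincRNAs tested, and of the falls 30 were among 4132 intronic transcripts. The largest rises lay in few loci: at XLOC_000218 the summed FPKM went from 113 ± 26.1 to 4183 ± 614, at XLOC_071240 from 45.9 ± 50.1 to 2626 ± 827 and at XLOC_000121 from 45.5 ± 28.1 to 1497 ± 325. The positions of these loci are not given here, so whether they overlap ribosomal or mitochondrial sequence could not be checked. All transcripts of this table summed to 4595 ± 307 FPKM in controls and 14350 ± 1473 with DMAG, and without 5 loci chosen after their values were seen to 4303 ± 283 and 4130 ± 383. LNC_000058 of XLOC_000218 was at 0.0397, 7.50 and 0 FPKM in the control libraries and at 2616 ± 653 with DMAG (adjusted p = 0.0046), and LNC_000915 fell from 3.05 ± 0.563 to 0.0250 ± 0.00941. LNC_002653 also fell (adjusted p = 0.0052). LNC_002238 was at 0.894, 1.44 and 1.14 FPKM in controls and listed at 0 with DMAG (adjusted p = 0.0054; 0.063 and 0.051 without control replicates 2 and 3). LNC_000063, LNC_003422 and LNC_000030 rose and LNC_000069 fell, each a call lost without at least 2 of the 6 libraries taken 1 at a time.

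Of 583 miRNAs, 125 were higher and 139 lower with DMAG (edgeR quasi-likelihood). Without scaling beyond the column total the split was 79 and 207, and DESeq2 gave 131 and 96. The miR-152 hairpin gave rises in both arms, hsa-miR-152-3p from 129 ± 9.79 to 589 ± 13.5 CPM (adjusted p = 3.9e-09) and hsa-miR-152-5p from 3.85 ± 0.921 to 23.0 ± 2.06. hsa-miR-450b-5p rose from 666 ± 57.3 to 2709 ± 95.1 CPM, hsa-miR-192-5p 3.64-fold, hsa-miR-1287-5p 3.95-fold and hsa-miR-190b-5p 3.61-fold. hsa-miR-92a-1-5p fell 2.83-fold and hsa-miR-7-5p from 20860.1 ± 4511 to 7715 ± 661 CPM; hsa-miR-3529-3p had nearly the same counts as the latter, so these 2 are uncertain as separate values. hsa-miR-548ag, hsa-miR-33b-3p and hsa-miR-760 fell 3.76-, 2.74- and 2.51-fold at low levels.

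Of the miRNA lists, that of monocytes and granulocytes had 9 of 12 higher and 3 lower (camera adjusted p = 0.0032, and adjusted p = 0.34 with an estimated correlation), with hsa-miR-223-5p 2.44-fold and hsa-miR-132-3p 3.55-fold higher. The megakaryocyte and platelet list had 7 of 18 higher and 3 lower (adjusted p = 0.025, and adjusted p = 0.34 with an estimated correlation), with hsa-miR-100-5p 1.96-fold and hsa-miR-222-3p 1.78-fold higher. These 2 lists are not separate results: they share hsa-miR-146a-5p, hsa-miR-146b-5p and hsa-miR-223-3p, 3 of the 7 that rose, and hsa-miR-27a-3p, which fell. hsa-miR-223-3p, a miRNA of platelets that is also abundant in myeloid cells, rose from 5908 ± 411 to 9228 ± 68.6 CPM. The miR-17-92 list with its paralogs had 3 of 11 lower and none higher (camera adjusted p = 0.42), hsa-miR-17-5p by 1.36-fold; hsa-miR-18a-5p and hsa-miR-106a-5p did not pass with RLE size factors (adjusted p = 0.071 and 0.10). For these 3 lists the counts were the same when adjusted over the list alone. The let-7 list had 4 of 9 higher and 2 lower (4 and 3 adjusted over the list alone; adjusted p = 0.64), with hsa-let-7b-5p not passing without scaling (adjusted p = 0.11). The erythroid list had 4 of 9 higher and none lower, or 4 and 2 adjusted over the list alone. It did not pass (camera adjusted p = 0.42), with a median log2 change of 0.16 and a mean of -0.13. hsa-miR-183-5p, 1.14-fold higher, had a log2 change of -5.9e-04 without scaling. Some members, chosen after their values were seen, were lower without passing over all miRNAs. hsa-miR-486-5p and hsa-miR-486-3p were each 1.64-fold lower (edgeR adjusted p = 0.063 and 0.065). Their counts were nearly the same, so these 2 are uncertain as separate values. hsa-miR-451a was 1.71-fold and hsa-miR-210-3p 1.64-fold lower (edgeR adjusted p = 0.12 and 0.081).

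**Figure D4:**
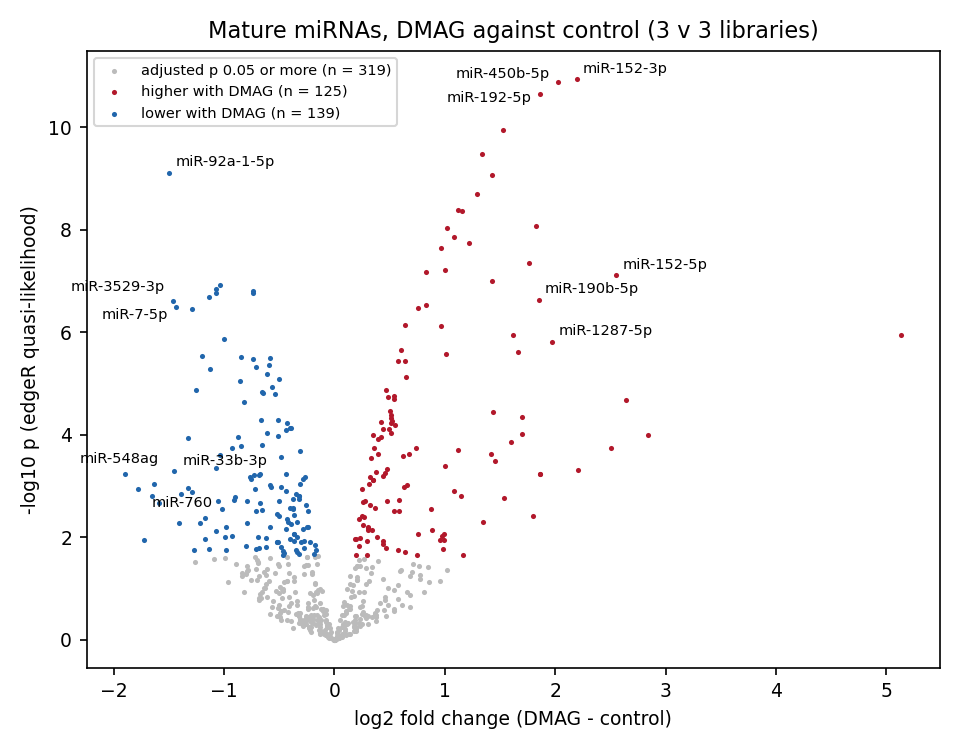
Log2 fold change of each of 583 miRNAs (x axis, DMAG minus control) against -log10 of the edgeR p (y axis); colours mark the 125 higher and 139 lower with DMAG. hsa-miR-152-3p lies at 2.19 and hsa-miR-92a-1-5p at -1.50.

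Of 303 circular RNAs tested, 2 were higher and 1 lower (edgeR; 36 had an unadjusted p under 0.05). The counts were low, with a median of 3 per library over all 943 circular RNAs. hsa_circ_0087357 had 13, 12 and 21 reads in the control libraries and 0 in each DMAG library (adjusted p = 0.0023). novel_circ_0004837 had 0 in each control library and 16, 9 and 10 with DMAG (adjusted p = 0.010), and hsa_circ_0067985 had 3, 0 and 5 against 26, 24 and 13 (adjusted p = 0.015). Without a filter on low counts edgeR called 0 of 943, with 76 under an unadjusted p of 0.05, while DESeq2 called 3 of the 303. Without DMAG replicate 1 only hsa_circ_0087357 passed, and hsa_circ_0067985 did not pass without control replicate 1 or 2 either (adjusted p = 0.061 and 0.059).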

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

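The alternative that leaves out 5 loci and that without RRP-named genes were chosen after the data were seen. The count of mRNA genes stayed between 4224 and 5135 under other pseudocounts, filters, scalings, the fit without trend, the block and each left-out library; it was 295 with a fold limit and 2774 per transcript, where fewer or other features are counted. Whether same-numbered libraries pair is not stated in the labels and was not settled here. Residual correlations of same-numbered libraries were -0.0048, 0.043 and 0.027 for mRNA, and 4 of 6 libraries (3 of 6 for miRNA) correlated best with their own number. With a replicate block the counts were 4491 mRNA genes, 254 annotated lncRNAs, 72 unannotated lncRNAs (65 higher and 7 lower), 247 miRNAs and 4 circular RNAs. Leaving out 1 library gave 206 to 330 annotated lncRNAs (206, 240 and 247 without DMAG replicates 1, 2 and 3), 64 to 98 unannotated ones (64 and 67 without DMAG replicates 1 and 2, 75 and 66 without control replicates 1 and 3), 202 to 259 miRNAs and 1 to 3 circular RNAs (1 without DMAG replicate 1). Circular RNAs were 0 without a filter and 1 at a mean count of at least 10. Gene lists passing were 0 with an estimated correlation and 27 with fry, which does not compare a list with other genes; fry also called the megakaryocyte and platelet (adjusted p = 9.8e-04), erythroid (0.011), DNA replication (0.013) and mitosis (0.030) lists. With camera at the preset correlation, adjusted p ranged from 0.12 to 0.28, 0.13 to 0.36, 0.38 to 0.65 and 0.073 to 0.21 for these 4. With an estimated correlation 0 miRNA lists passed. Per transcript the most abundant transcript of MCM4 (0.90), MLX (0.61) and STEAP3 (0.22) had a log2 change above 0 and that of NDRG1 (-0.17) below 0, each against its gene, and hsa-miR-183-5p (-5.9e-04) turned without scaling; the cause was not tested. Of the values of single named genes and lists, leaving out 1 library left 1325 with the same call, ended 68 and added 2; the other alternatives left 1757, ended 172, added 16 and turned 5. The list of ribosome biogenesis genes without RRP-named members had an adjusted p of 1.94e-10, and 102 unannotated lncRNAs passed without the 5 loci. The unknown depth of the FPKM tables and the few reads per circular RNA limit the low values.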

Other observations

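Tests chosen only after their results were seen are those of RRP-named genes, of the ribosome biogenesis list without them, of the other mitochondrial mRNAs, of HBB by library and of the lineage transcripts; the others were set beforehand. In this paragraph and the next, the decimal beside each list's counts is its camera adjusted p. Glycolysis genes had 11 of 19 lower and 5 higher (camera adjusted p = 0.13) with HK2 1.66-fold lower and SLC2A3, a glucose transporter, 3.39-fold higher. Hypoxia response genes had 9 of 20 lower and 5 higher (9 and 6 adjusted over the list alone; 0.30), DDIT4 2.43-fold lower; LDHA and SLC2A1, chosen after their values were seen, are among the lower genes of both lists. Cholesterol synthesis genes had 8 of 23 lower and 1 higher (0.091, or 0.029 without DMAG replicate 3), ACAT2 1.87-fold lower. NF-kB targets had 9 of 15 higher and 3 lower (0.13), CCL5 2.23-fold higher. Granulocyte genes went both ways, 8 of 17 higher and 7 lower (9 and 7 adjusted over the list alone; 0.71), a median log2 change of 0.27 and a mean of -0.03, with PRTN3 and EPX (2.03-fold) lower and BPI (2.14-fold) higher.

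Of the other lists, JAK-STAT targets had 9 higher and 4 lower of 18 (camera adjusted p = 0.30), stem and progenitor genes 4 and 1 of 8 (0.091; 3 of the 4, GATA2, LMO2 and MYB, noted after their values were seen, are also in the transcription factor list), and integrin and matrix genes 8 and 5 of 16 (0.27). Nuclear oxidative phosphorylation genes had 5 and 15 of 40 (0.23), NRF2 targets 5 and 5 of 20 (0.97, with a median log2 change of -0.01 where camera points up), iron handling 3 and 2 of 13 (0.81), MYC and its partners 2 and 3 of 8 (0.98, with a median of -0.16 where camera points up), and BCL2 family (0.98) and heme synthesis genes (0.98; median -0.08, mean 0.04) 2 and 2 of 12 each. For the lists here with no second count it was the same adjusted over the list alone. Lymphocyte genes, 2 and 2 of 4, and aryl hydrocarbon receptor targets, 0 and 3 of 4, were too few for a list test. The 13 mitochondrially encoded genes had 4 higher and 6 lower (4 and 8 adjusted over the list alone), a median log2 change of -0.27 and a mean of 0.88 (0.98).

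Genes named for ribosomal RNA processing and the 3 mitochondrial mRNAs MT-ND5, MT-ND6 and MT-CYB were many-fold higher with DMAG, while most other genes of the same processes were not. A general rise of ribosome biogenesis is argued against by the median log2 change of -0.47 of the 42 list members not named RRP, one of ribosomal RNA processing by the -0.21 of 13 RNA exosome genes, and one of mitochondrial transcription by the -0.35 of the other 10 mitochondrial mRNAs, although MT-ND4 rose 2.04-fold. A candidate explanation is that reads taken for ribosomal RNA, by name or sequence, were removed from the control libraries alone. With no filter on level, all 8 RRP-named genes were at least 4-fold higher, among them RRP15 (20.7-fold) and RRP8 (6.93-fold). That count describes the pattern and is no support for the explanation, since the names were chosen after their rises were seen. A test of these names at a mean of at least 5 FPKM (Fisher's exact test, two-sided, p = 2.8e-15) supports nothing, since the names were those that drew attention and the mean includes the raised values: the 6 genes counted were at 1.17 to 2.84 FPKM in controls. Of genes chosen after their values were seen, as RRP15 and RRP8 were, FTSJ1 (4.89-fold) and RRNAD1 (3.39-fold) also rose, FTSJ3 fell 1.17-fold and MRM1 and MRM3 did not pass (log2 change 0.07 and -0.14), and removal cannot be told apart from an effect of DMAG since it would follow the groups.

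Adult globins in DMAG replicate 3 were HBB at 1367, HBA1 at 375 and HBA2 at 199.6 FPKM, with ALAS2 at 4.04, all 4 chosen after their values were seen. Induction by DMAG is argued against by the other DMAG libraries, where HBB was at most 0.0731 FPKM. RNA of blood cells in this library may account for it: of 77 monocyte, granulocyte and lymphocyte genes, 6 (FCGR3A, FCGR3B, CD3D, CD8A, IL7R and CD22, at 0.0519 to 0.286 FPKM) reached 0.05 FPKM there alone, against at most 1 in any other library, while 39 of the 77 reached it in all 6. Foreign RNA in a sample that also gave the small RNA library was tested by hsa-miR-451a, a red cell miRNA. In DMAG replicate 3 it was 0.39 times the highest of the other 5 libraries, control replicate 2 (14.8 and 37.6 CPM of all counts). Control replicates 1 and 3 were at 17.2 and 12.5, and DMAG replicates 1 and 2 at 12.7 and 6.16. DMAG replicate 3 was thus the highest of its group, so the result argues only against an excess over all other libraries. The labels do not say whether both libraries came from 1 RNA sample.

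In all 6 RNA-Seq libraries, GATA1, ITGA2B, ITGB3 and GP1BA were near 0 and the granule genes MPO and PRTN3 high, though ELANE was at 17.2 FPKM or less on average, under a label naming HEL. Whether these are failed estimates of expressed genes stays open: no transcript of them exceeded 0.302 FPKM, but they were picked for low sums over transcripts. Cells of another line could give such levels; the test on hsa-miR-451a, at 22.4 ± 13.4 CPM of all counts in the control small RNA libraries, lay between the limits set beforehand, so another line and HEL with low lineage genes cannot be told apart. Loss of these genes in the cultured line was not tested, and no HEL reference was used here.

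The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In each case 1 split, the real one, gave a result as large. For gene lists at the preset correlation the margin was only 10 against 9, so that count barely set the real groups apart. The real and the highest other count were 5050 and 1 for mRNA genes, 442 and 3 for annotated lncRNAs, 113 and 3 for unannotated ones, 264 and 0 for miRNAs, 3 and 1 for circular RNAs, 2 and 1 for miRNA lists, and 10 and 9 for gene lists.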
